A study of Homo sapiens with 8 samples.

How the data were processed

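RNA-seq was analysed in 8 libraries of WS1, an established line of human skin fibroblasts. Per the labels' protocols, 4 libraries came from cells given a lentivirus that overexpresses IFI6 and 4 from cells given a negative-control lentivirus labelled NC. All cells received 5 Gy of X-rays at 1.15 Gy per min and were collected 24 h later. Ribosomal RNA was removed and directional libraries were made with NEBNext kits and sequenced on an Illumina HiSeq, per the labels' protocols. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cufflinks, Cuffdiff and the genome build hg19, without their order; these tools are in general used to trim reads, align them and estimate transcript levels. Whether counting used the strand is not given in the sources used here.

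The authors deposited 1 table with 20307 genes, all of them annotated as protein-coding, and 2 values per gene and library. The first is FPKM, which the authors deposited as fragments scaled for transcript length and for the mapped fragments of the library, as named in the file headers. The second is an estimated count that the authors had already scaled: in each library about 90% of its positive values (89.9% to 90.9%) are whole multiples of 1 constant within a tolerance of 0.01. That constant, the most frequent value of the library, lay between 0.534 and 1.45. Dividing by it and rounding to whole numbers restored fragment counts, whose totals were 1761831 to 4725224 per library. The scaled totals lay between 2508550 and 2614510. Each library's columns were matched to its sample by name. The columns of the libraries labelled IFI6 spell the gene IF16. The table gives 1 hg19 interval per gene, and genes that overlap can share 1 interval, so fragments of overlapping genes can be split between them by estimation.

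Before the data were examined, the tests, the gene lists, the rule for named genes and the other settings to try were fixed. IFI6 was compared with an exact two-sided permutation test on log2(FPKM + 1) over all 70 assignments of 8 libraries into groups of 4. The smallest p this can give is 0.0286. All genes with a mean FPKM of at least 1 were tested with limma 3.58.1 (empirical Bayes with a variance trend, two-sided) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. IFI6 itself was left out of the counts, which leaves 11673 genes. A log2 difference on this scale understates the change of genes with low values. The design chose limma for FPKM and a count model in case the table held counts. As the table holds both, and its counts had been scaled, limma stayed the main test and the count models were run as alternatives on the restored counts: edgeR 4.0.16 (quasi-likelihood test, TMM scaling, low counts filtered) and DESeq2 1.42.0. R 4.3.3 and Python 3.11.15 were used.

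For 23 gene lists, limma's camera tested whether members differed from the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists. Lists needed at least 5 members past the filter. Camera with an estimated correlation and fry, which tests whether members move on balance one way, were alternatives. The lists were interferon-stimulated genes, antigen presentation, p53 targets, mitosis, DNA replication, double-strand break repair, replication-dependent histones, heat shock factor targets, the unfolded protein response, NRF2 antioxidant targets, NF-kB cytokines, collagens and matrix, matrix proteases and inhibitors, the TGF-beta myofibroblast programme, apoptosis, nuclear and mitochondrially encoded respiratory chain genes, mitochondrial DNA maintenance, cholesterol and lipid synthesis, glycolysis and hypoxia, ribosomal proteins, autophagy and lysosome, and immediate early genes. There were 7 marker lists: keratinocyte, melanocyte, endothelial, immune, smooth muscle and pericyte, adipocyte and fibroblast.

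The rule for named genes took IFI6, then up to 12 rises and 12 falls among genes that passed and whose groups did not overlap. It also took the 4 members with the smallest unadjusted p from each list that passed and, whether or not they passed, from the interferon, p53, break repair, heat shock and mitochondrial DNA maintenance lists. Genes on the Y chromosome, XIST and TSIX were never named. A few genes that the rule chose are not reported here and do not enter the counts of named genes.

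Other pseudocounts, filters, scalings, moderation settings, library weights, a block by replicate number, and leaving out each library were the other settings. A restriction to protein-coding genes moved nothing, as all genes in the table are protein-coding. Further settings were added after seeing the data: leaving out libraries 1 and 2 labelled IFI6 together, removing each library's trend with GC content by loess (span 0.3), median-ratio scaling for the count of genes whose groups do not overlap, and an estimated correlation within each of the other settings for lists. GC content is the median over a gene's protein-coding transcripts in GENCODE 29, matched by gene identifier for 18836 genes and by symbol for 314. GENCODE 29 is built on another genome build, so no coordinates were taken from it.

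The procedure was tested on simulated counts of 10603 genes with the means and dispersions of these libraries, for the comparison of the libraries labelled IFI6 with NC. With 100 genes changed 2-fold, limma and edgeR each recovered 35%. With 100 genes changed 4-fold each recovered 91%. Limma made 6 false calls and edgeR 5. A list lowered by 0.5 on the log2 scale passed camera (adjusted p = 1.22e-18) with no other list called. The simulated genes were drawn independently of each other, so this cannot show how camera's preset correlation fares with correlated genes. The shift was also larger than the median shift, relative to all genes, of any list that passed in the real data. Fragments without molecular identifiers are not independent molecules. The labels do not say whether libraries of a group come from separate cultures, so p-values measure only the spread between these libraries, which may be technical.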

Results

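Gene expression was measured by RNA-seq in WS1 cells, an established line of human skin fibroblasts, 24 h after 5 Gy of X-rays given at 1.15 Gy per min. Before irradiation the cells had received a lentivirus that overexpresses IFI6 or a negative-control lentivirus labelled NC, with 4 libraries each. IFI6 is an interferon-inducible gene whose protein is known as an inhibitor of apoptosis. Restored fragment counts totalled 2057338 to 2269031 in the NC libraries. In replicates 1 to 4 labelled IFI6 they were 2240310, 4725224, 1761831 and 3044184. The comparison asks how irradiated fibroblasts with added IFI6 differ from irradiated fibroblasts without it. All 8 libraries were irradiated, so a response to radiation itself cannot be read from them.

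IFI6 was not higher in the libraries labelled IFI6. The gene (ENSG00000126709) lies on the minus strand of chromosome 1, from 27992571 to 27998729 in hg19. Its level was 24.98 ± 4.75 FPKM (SD, n = 4) in the NC libraries and 18.8 ± 6.22 FPKM (SD, n = 4) in the libraries labelled IFI6. The NC libraries held 20.3, 31.3, 22.6 and 25.6 FPKM, and those labelled IFI6 held 21.7, 13.9, 13.4 and 26.2 FPKM. The difference was -0.43 on the log2(FPKM + 1) scale (exact permutation test, two-sided, p = 0.2, smallest possible p 0.0286). Limma's 95% interval for the ratio, IFI6 over NC, ran from 0.506 to 1.09. The deposited value of the gene therefore goes against the label, and every direction given here is that of the libraries labelled IFI6 relative to NC, not of measured IFI6. Values at IFI6 rested on 18 to 62 fragments per library.

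**Figure D1:**
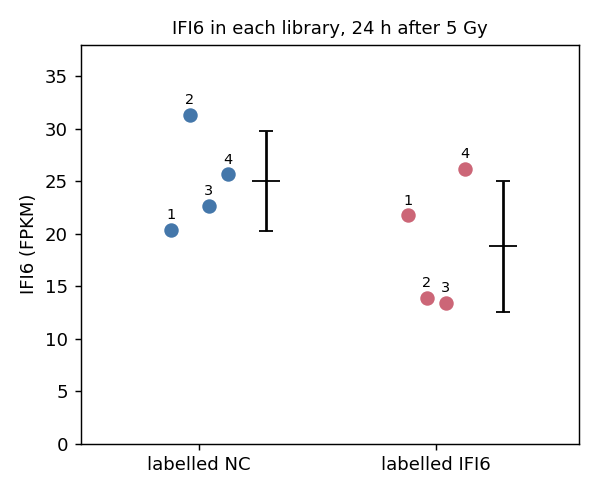
IFI6 in FPKM (vertical axis) in each library, by the group of its label (horizontal axis). Points are single libraries with their replicate number, and the bar beside them is the mean ± SD of 4 libraries. The NC libraries lie between 20.3 and 31.3 FPKM and those labelled IFI6 between 13.4 and 26.2 FPKM, so the groups overlap.

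No gene passed the adjusted threshold in limma, neither IFI6 (adjusted p = 0.522) nor any of the 11673 other genes tested. At an unadjusted p under 0.05 there were 1338 genes, 113 higher and 1225 lower in the libraries labelled IFI6, and the smallest adjusted p was 0.380. The split follows the scale: the median difference over all genes was -0.16, and with median-ratio scaling it was 0.02, with 500 of 987 such genes higher. Relative to the NC mean, the median over all genes was -0.15, -0.49, -0.04 and -0.03 in libraries 1 to 4 labelled IFI6. Changes of gene groups are therefore given relative to the median of all genes. On restored counts, edgeR's quasi-likelihood test called 0 of 10602 genes, with 1217 at an unadjusted p under 0.05. DESeq2 called 15 genes as higher and none as lower, among them HNRNPA2B1 and HNRNPDL, which encode RNA-binding proteins, and the mitochondrially encoded MT-ND2, MT-ND5 and MT-CO3. The adjusted p of DESeq2 was 0.000771 for HNRNPA2B1 and 1.93e-06 for HNRNPDL. The genes HNRNPA2B1, HNRNPDL and MT-ND2 were chosen after their values were seen. The groups did not overlap in 1049 genes, 983 lower and 66 higher in the libraries labelled IFI6, or 8.99% of those tested against 2.86% by chance. With median-ratio scaling, a setting added for this count after seeing the data, there were 698 such genes (5.98%), 345 lower and 353 higher, so the lopsided split also follows the scale.

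Library 2 labelled IFI6 stood apart. It held 345 genes at least 4-fold above every other library, on the log2(FPKM + 1) scale, and they took 12.7% of its fragments. Library 1 labelled IFI6 held 101 such genes with 3.81% of its fragments, against 10 and 11 in the libraries 3 and 4 and 1 to 5 in each NC library. The median SD within the group was 0.24 on the log2 scale in NC and 0.40 in the libraries labelled IFI6. Without libraries 1 and 2 labelled IFI6, a choice made after seeing the data, limma called 30 genes, 17 higher and 13 lower. In the same libraries edgeR called 429 genes, 300 higher and 129 lower, and 18 genes were called by both. Both called DEK, a chromatin protein, and the mitochondrially encoded MT-ND6 higher. Of the genes for ribosomal proteins, both called RPS15 and RPL10 lower and RPS24 higher. Limma's log2 differences there were 1.32 for DEK, 1.23 for MT-ND6, -0.86 for RPS15, -0.64 for RPL10 and 0.53 for RPS24 (adjusted p = 0.0167, 0.0167, 0.0310, 0.0406 and 0.0472). In edgeR they were 0.72, 1.44, -0.65, -0.37 and 0.76 in the same order. GC content was 41.9%, 42.7% and 44.1% in the higher DEK, MT-ND6 and RPS24, and 62.1% and 54.6% in the lower RPS15 and RPL10. Against this, limma called RPS23 lower at 43.8% and HNRNPM higher at 53.1%. Library 3, which remains in this setting, had the strongest GC trend (Spearman's rho = -0.39 relative to the NC mean). The GC trend was not removed here, so its part in these calls was not tested. Apart from MT-ND6, these genes were chosen after their values were seen.

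Of the 23 lists, 5 passed camera with its preset correlation, 4 lower and 1 higher in the libraries labelled IFI6. With an estimated correlation none of the 5 passed (adjusted p = 0.887 for each). The adjustment gave the same value to lists that had not passed, so it does not rank the lists. Fry called none (smallest adjusted p = 0.112). An estimated correlation was also combined with each of 18 other settings, after seeing the data, and no list passed in any of them (smallest adjusted p = 0.338). The number of lists depended on single libraries: it was 2 without library 3 labelled IFI6, and 3 without NC replicate 2, 3 or 4. Upper-quartile or median-ratio scaling left 3 lists, the histones, glycolysis and the mitochondrially encoded genes. In edgeR on restored counts, where no list was tested, the median log2 difference over all genes was 0.02. Over members it was -0.13 for histones, -0.09 for glycolysis, -0.04 for nuclear oxidative phosphorylation, -0.07 for cholesterol synthesis and 0.50 for mitochondrially encoded genes. The falls were thus smaller on counts than on FPKM. The difference of a gene between the groups also followed its GC content across 11548 genes (Spearman's rho = -0.34 across genes, which are not independent replicates). The trend was uneven: relative to the NC mean, rho was -0.09, -0.26, -0.39 and -0.17 in libraries 1 to 4 labelled IFI6, while that of each NC library relative to the other 3 was 0.00, 0.08, -0.16 and 0.08 in replicates 1 to 4. The median difference was -0.01 in the fifth of genes with the lowest GC and -0.31 in the fifth with the highest in limma's values. In the lists below, members are counted by the sign of their difference. The median over all genes was -0.16, so most genes were negative and these counts carry the scale. Among lists that did not pass, 17 of 18 antigen presentation and 22 of 26 collagen and matrix genes were negative, but 16 of 31 break repair genes.

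**Figure D2:**
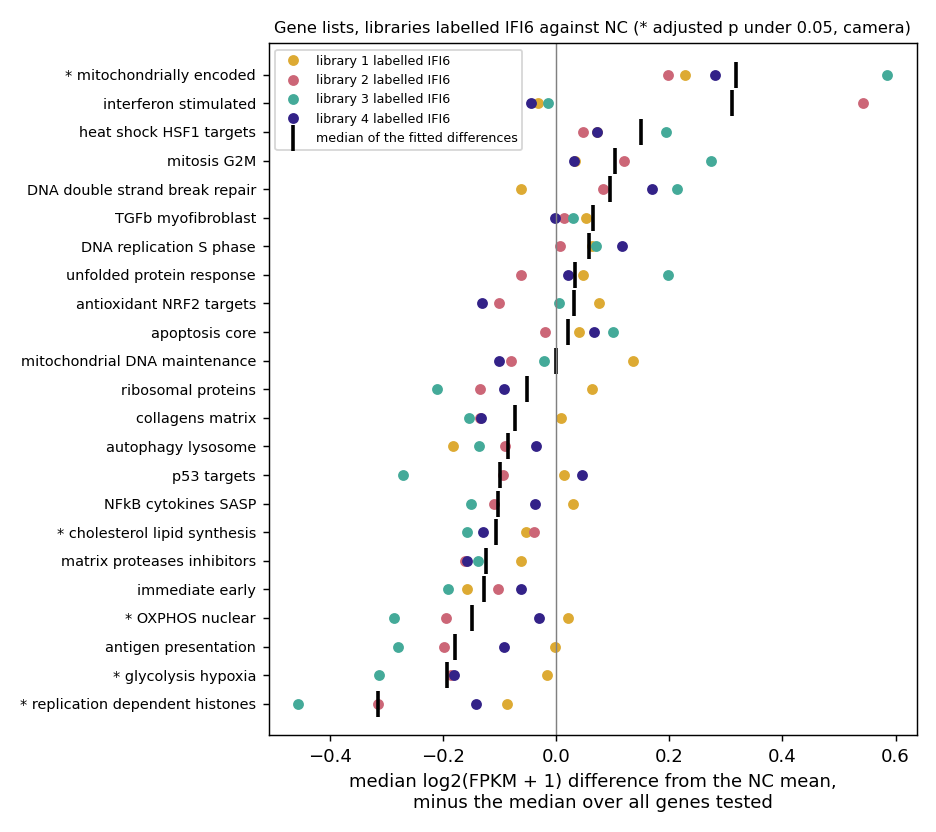
Gene lists (vertical axis) by their median log2(FPKM + 1) difference from the NC mean, minus the median over all genes tested (horizontal axis). Points are the 4 libraries labelled IFI6, black bars the median of the fitted differences over members, and asterisks lists past camera's threshold. The interferon list stands at 0.54 in library 2 and between -0.04 and -0.01 in the other 3.

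The replication-dependent histones, which package newly made DNA in S phase, were lower as a list in the libraries labelled IFI6 (camera adjusted p = 4.72e-05, 0.887 as the p with an estimated correlation). Of 26 measured members 24 had a negative difference, and the median was -0.31 relative to that of all genes. In limma with all libraries no member passed over all genes, and 0 passed adjusted over the list alone. Without libraries 1 and 2 labelled IFI6, HIST1H4C passed as lower in limma (adjusted p = 0.0406) and in edgeR (0.0427). HIST1H4C was at 141 ± 15.2 FPKM in NC and 74.4 ± 28.5 FPKM in the libraries labelled IFI6 (SD, n = 4 each). HIST1H3B was at 178 ± 14.2 and 118 ± 25.7 FPKM, HIST1H1C, a linker histone, at 321 ± 24.2 and 235 ± 20.6 FPKM, and HIST1H3C at 140.5 ± 14.01 and 93.3 ± 26.3 FPKM. In these 4 genes each NC library was above each library labelled IFI6, and limma's adjusted p was 0.380. Histone genes have near-identical copies, so values of single members are uncertain. The median GC content of the list was 55.3%.

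Glycolysis and hypoxia genes were also lower as a list (camera adjusted p = 0.00594, 0.887 as the p with an estimated correlation), with 21 of 25 members negative and a median of -0.19 relative to all genes. VEGFA, an angiogenic growth factor, was at 100.3 ± 9.90 FPKM in NC and 59.2 ± 12.9 FPKM in the libraries labelled IFI6. It was the 1 member that fell when adjusted over the list alone (adjusted p = 0.0485 in limma, 0.380 over all genes). The glycolytic enzymes GAPDH (3092 ± 132 against 2215 ± 381 FPKM) and TPI1 (786 ± 23.3 against 567 ± 97.1 FPKM) and the glucose transporter SLC2A1 (45.9 ± 4.38 against 31.0 ± 6.33 FPKM) did not pass over all genes in limma. In all 4 genes the groups did not overlap. The list no longer passed without library 3 labelled IFI6 (adjusted p = 0.0619), and its median GC content was 55.8%.

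The 2 lists of the respiratory chain went apart. Mitochondrially encoded genes were higher as a list (camera adjusted p = 0.0138, 0.887 as the p with an estimated correlation), with 8 of 12 members positive and a median of 0.32 relative to all genes. In limma none passed over all genes or adjusted over the list alone, while DESeq2 called MT-ND2, MT-ND5 and MT-CO3 higher (adjusted p = 0.0124, 0.0308 and 0.0200). Of the named members, MT-CO1 went the other way, with 5453 ± 719 FPKM in NC and 3019 ± 1356 FPKM in the libraries labelled IFI6. MT-CO3 was at 2466 ± 209 and 3351 ± 990 FPKM, MT-ND5 at 4296 ± 262 and 5359 ± 1326 FPKM, and MT-ND6 at 1271 ± 77.3 and 2091 ± 1127 FPKM. MT-ND5 and MT-ND6 lie on opposite strands and share an interval in the table, so their values are uncertain. Libraries 1 to 4 labelled IFI6 held 4.17%, 3.10%, 4.82% and 3.78% of their fragments in the mitochondrially encoded genes, against 3.40% to 3.73% in the NC libraries. Nuclear genes of oxidative phosphorylation were lower as a list (camera adjusted p = 0.0449, 0.887 as the p with an estimated correlation), with 30 of 40 members negative and a median of -0.15 relative to all genes. The ATP synthase subunit ATP5A1 was at 111 ± 7.92 and 70.8 ± 12.1 FPKM, CYC1 at 88.3 ± 7.65 and 54.0 ± 12.1 FPKM, SDHC at 51.2 ± 4.88 and 33.0 ± 7.27 FPKM, and COX8A at 315 ± 36.4 and 202 ± 65.0 FPKM. In limma none of the 40 members passed over all genes, and 0 passed adjusted over the list alone. Without library 3 labelled IFI6 neither list passed (adjusted p = 0.275 for the nuclear and 0.0747 for the mitochondrially encoded list). The nuclear list was also lost without library 2 labelled IFI6 (0.111), without NC replicate 2, 3 or 4 (0.175, 0.0673 and 0.0569), with upper-quartile or median-ratio scaling, with the replicate number as a block and with a mean FPKM of at least 5. The mitochondrially encoded list was also lost with quantile normalization (0.343) or no filter (0.0690).

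Cholesterol and lipid synthesis genes passed narrowly (camera adjusted p = 0.0457, 0.887 as the p with an estimated correlation). Of 27 members 24 were negative, with a median of -0.11 relative to all genes, and 0 passed in limma over all genes or adjusted over the list alone. ACLY, which makes cytosolic acetyl-CoA, was at 124 ± 3.25 FPKM in NC and 97.3 ± 11.8 FPKM in the libraries labelled IFI6, and LSS at 28.4 ± 2.22 and 20.2 ± 6.44 FPKM. The call was lost when library 1, 3 or 4 labelled IFI6 (adjusted p = 0.0973, 0.0722 and 0.0659) or NC replicate 1, 2, 3 or 4 (0.0620, 0.175, 0.0726 and 0.0569) was left out, and without libraries 1 and 2 labelled IFI6 (0.121). It was also lost with upper-quartile or median-ratio scaling, with the replicate number as a block and with a mean FPKM of at least 5.

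Interferon-stimulated genes did not pass (camera adjusted p = 0.0603, higher), with 22 of 40 members positive, 0 past limma's threshold over all genes and 0 adjusted over the list alone. Library 2 labelled IFI6 set the direction: the list's median relative to all genes was 0.54 there and -0.03, -0.01 and -0.04 in libraries 1, 3 and 4. The list passed as higher with a mean FPKM of at least 5 (adjusted p = 0.0249), with the replicate number as a block (0.0376), without NC replicate 1 (0.0198) and without library 1, 3 or 4 labelled IFI6 (0.0120, 0.0159 and 0.0304). Without library 2 labelled IFI6 the adjusted p was 0.370. With an estimated correlation it was 0.887 with all libraries, and 0.804 to 0.990 in the settings where the list passed at the preset correlation. The 4 members with the smallest p were all lower. ISG20, an interferon-inducible exonuclease, was at 32.9 ± 7.18 FPKM in NC and 16.98 ± 3.51 FPKM in the libraries labelled IFI6, and UBE2L6 was at 54.4 ± 7.07 and 38.3 ± 2.56 FPKM. ISG15, the ubiquitin-like protein that UBE2L6 helps to attach, was at 52.3 ± 9.14 and 36.4 ± 4.06 FPKM, and IFITM2 was at 43.3 ± 3.82 and 31.7 ± 4.22 FPKM. In these 4 genes each NC library was above each library labelled IFI6, while limma's adjusted p was 0.380 to 0.389. Limma's log2 differences were -0.91 for ISG20, -0.49 for UBE2L6, -0.50 for ISG15 and -0.44 for IFITM2. In edgeR on restored counts they were smaller, at -0.71, -0.27, -0.24 and -0.13. IFIH1, a sensor of double-stranded RNA chosen after its values were seen, was at 809 FPKM in library 2 and between 5.09 and 9.82 FPKM in the other libraries.

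**Figure D3:**
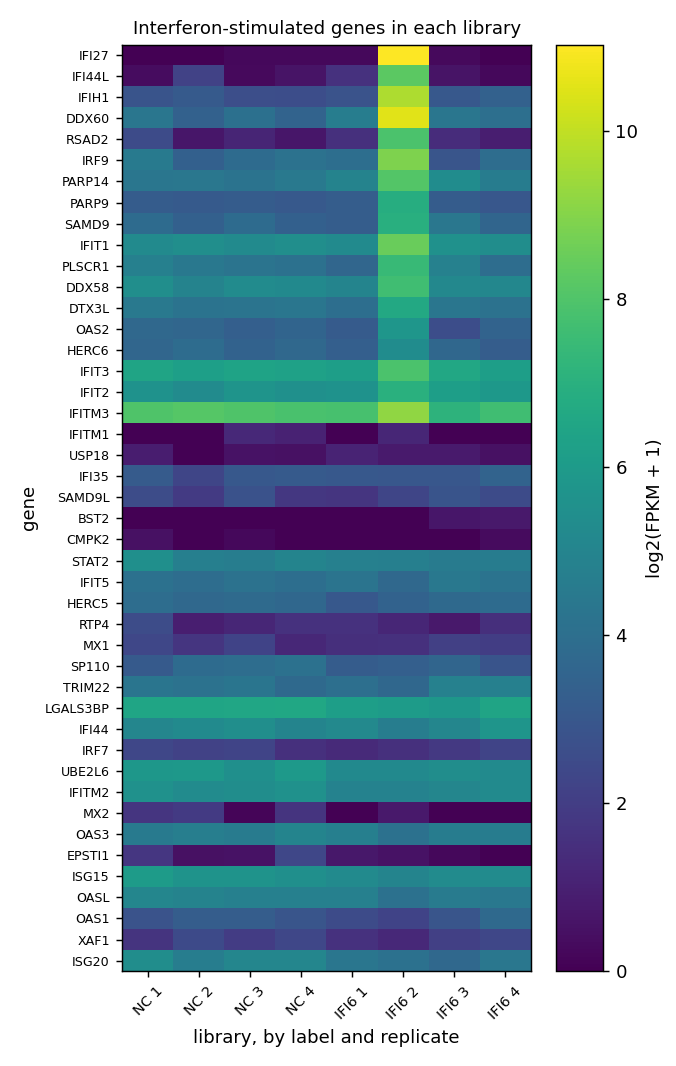
Interferon-stimulated genes (rows) in each library (columns, by label and replicate), coloured by log2(FPKM + 1) and ordered by the difference of library 2 labelled IFI6 from the NC mean. IFI27 is at 2088 FPKM in that library and at most 0.215 FPKM in the other 7, while ISG15 and ISG20 are lower there than in each NC library.

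The other lists from which the rule took genes whether or not they passed did not differ by camera's test. For p53 targets (29 measured, 9 positive) the adjusted p was 0.916. PLK3 was at 22.3 ± 5.18 FPKM in NC and 15.0 ± 4.18 FPKM in the libraries labelled IFI6, RPS27L at 78.6 ± 13.3 and 60.2 ± 10.7 FPKM, TRIAP1 at 25.8 ± 3.49 and 18.8 ± 5.89 FPKM, and AEN at 31.9 ± 3.96 and 24.3 ± 6.74 FPKM. For double-strand break repair (31 measured, 15 positive) the adjusted p was 0.222. The checkpoint kinases CHEK2 and CHEK1 were at 11.1 ± 4.04 and 29.05 ± 3.13 FPKM in NC and at 6.50 ± 2.12 and 19.8 ± 8.63 FPKM in the libraries labelled IFI6. The recombination genes XRCC3 (47.3 ± 4.86 against 36.2 ± 10.6 FPKM) and RAD54L (15.2 ± 2.21 against 11.98 ± 2.42 FPKM) overlapped between the groups. For heat shock factor targets (24 measured, 11 positive) the adjusted p was 0.522. HSPE1, a mitochondrial co-chaperone, was at 119 ± 25.9 and 225 ± 119 FPKM with 399.7 FPKM in library 2. HSPA1B was at 14.7 ± 1.64 and 9.23 ± 1.30 FPKM and the collagen chaperone SERPINH1 at 117 ± 6.18 and 89.1 ± 15.1 FPKM. HSPA1B has a near-identical copy, so its value is uncertain. For mitochondrial DNA maintenance (14 measured, 6 positive) the adjusted p was 0.879, with TFB1M at 8.12 ± 0.967 and 5.30 ± 0.787 FPKM, TFB2M at 7.56 ± 2.24 and 5.01 ± 0.501 FPKM, DGUOK at 33.0 ± 4.15 and 23.3 ± 8.59 FPKM, and C10orf2, the mitochondrial helicase, at 5.52 ± 2.85 and 3.11 ± 1.096 FPKM. None of these genes passed over all genes in limma, nor did any pass adjusted over the list alone.

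Among the 37 genes named by the rule besides IFI6, limma's adjusted p ranged from 0.380 to 0.545, 33 were lower, and in 21 the groups did not overlap. The rule took the members with the smallest p in these same data, so direction and lack of overlap follow in part from the choice. These counts also carry the scale: 8.99% of all genes tested did not overlap, 983 lower and 66 higher. With median-ratio scaling it was 345 lower and 353 higher. The same limits hold for the single genes said above not to overlap. Without libraries 1 and 2 labelled IFI6, limma called HIST1H4C and MT-ND6 of the 37 named genes, and edgeR called 11 (adjusted p = 1.22e-06 to 0.0460): HSPE1, MT-CO3, MT-ND5 and MT-ND6 higher, and HIST1H4C, VEGFA, GAPDH, TPI1, MT-CO1, ATP5A1 and CYC1 lower. Of the 38 named genes 18 share their interval with another gene in the table, so fragments of overlapping genes can enter their values: TFB1M, RAD54L, C10orf2, TPI1, HSPE1, XRCC3, CHEK1, ATP5A1, LSS, TRIAP1, PLK3, COX8A, CHEK2, RPS27L, IFITM2, MT-ND6, MT-ND5 and MT-CO3.

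The other lists did not pass camera. The adjusted p was 0.102 for matrix proteases and inhibitors, 0.128 for antigen presentation, 0.179 for collagens and matrix, 0.199 for mitosis, 0.205 for immediate early genes and 0.238 for autophagy and lysosome. It was 0.321 for ribosomal proteins, 0.584 for NF-kB cytokines, 0.599 for apoptosis and for DNA replication, 0.782 for the unfolded protein response, 0.916 for the TGF-beta programme and 0.973 for NRF2 targets. Of these lists, ribosomal proteins passed as lower without library 2 labelled IFI6 (0.00735), without libraries 1 and 2 labelled IFI6 (2.70e-06, the smallest of the 23 lists there) and with quantile normalization (1.51e-05). Matrix proteases and inhibitors (0.0316) and autophagy and lysosome (0.0420) also passed as lower without library 2 labelled IFI6, and both with quantile normalization (0.00128 and 0.0167). Antigen presentation passed as lower with quantile normalization (0.0167) and with no filter (0.0419), and matrix proteases and inhibitors with no filter (0.0409). All these calls rest on the preset correlation: with an estimated correlation in the same settings none of the lists passed, and the adjusted p of ribosomal proteins was 0.652 without library 2, 0.543 without both and 0.414 with quantile normalization. The NRF2 and mitochondrial DNA maintenance lists had a median above that of all genes while camera's direction was lower. Among the genes of these lists that fell when adjusted over the list alone, all named after their values were seen, were the ribosomal protein RPS15 (922 ± 79.2 FPKM in NC and 545 ± 99.8 FPKM in the libraries labelled IFI6), the pro-apoptotic BAD (43.1 ± 5.26 and 24.9 ± 2.72 FPKM), the growth factor TGFB2 (2.80 ± 1.37 and 0.381 ± 0.295 FPKM) and the endoplasmic reticulum protein SDF2L1 (13.3 ± 2.29 and 6.05 ± 1.84 FPKM). Their limma adjusted p over all genes was 0.380.

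Fibroblast markers were expressed in both groups, and the list did not differ (camera adjusted p = 0.386, 9 of 10 markers past the filter). VIM was at 1693 ± 25.2 FPKM in NC and 1498 ± 242 FPKM in the libraries labelled IFI6, and THY1 at 358 ± 26.8 and 286 ± 58.5 FPKM. The other marker lists had fewer than 5 members past the filter and were not tested. Of the keratinocyte markers, KRT5, KRT14 and KRT1 were listed at 0 in each library, while TP63 and SFN reached 73.1 and 313 FPKM in library 2 labelled IFI6 and at most 0.108 and 1.38 FPKM in the others. The highest mean over all libraries was 6.10 FPKM among melanocyte markers (MITF), 5.25 FPKM among endothelial markers (TIE1), 17.8 FPKM among smooth muscle and pericyte markers (CSPG4) and 12.8 FPKM among adipocyte markers (PPARG). Among immune markers CD68, which fibroblasts also express, was at 90.6 FPKM and no other marker had a mean of 1 FPKM.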

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

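The tests of exchanged labels, IFI6 depth, transgene fragments, depth of library 1 and keratinocytes were chosen after their results were seen. So were those of fragments on a short part of a gene and of the omission of libraries 1 and 2. The other splits for genes passing and for genes at an unadjusted p under 0.05 were also chosen after their results were seen. The tests of depth of library 2, a shared response, GC content and the other splits for lists passing were set before their own results were seen. Even so, the GC correction was added after seeing the data, and the tests on library 2 address a pattern already seen in it. Among 136 groups of 4 values tested for a library far from the others of its group (Dixon's ratio above its 95% critical value), 5 were found, and 6.8 are expected by chance. ACLY in library 2 labelled IFI6 was 79.8 FPKM against 101 to 105 FPKM in the other 3. The median log2(FPKM + 1) of the antigen presentation list was 5.50 in NC replicate 3 against 5.64 to 5.67 in the other NC libraries. NC replicate 4 had 11613 genes of at least 1 FPKM against 11661 to 11662. On the first principal component, NC replicate 2 stood at -15.4 against -13.6 to -13.2. On the same component, which held 40.5% of the variance, library 2 labelled IFI6 stood at 92.7 against -15.6 to -8.58 in its group.

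IFI6 was not higher in the libraries labelled IFI6. Exchanged labels of single libraries would leave a library labelled NC with a high value, if the construct raised the value counted at IFI6. The highest NC library was 1.41 times the median of the 8. As no library held a high value, the test cannot decide where transgene fragments were not counted or IFI6 was not raised. An exchange of the whole groups was not tested. Low depth is argued against, since the upper 95% bound of the ratio was 1.09, and 1.19 with median-ratio scaling, below a 2-fold rise. Transgene fragments may have been left uncounted, for instance where they align outside the annotated gene: the table holds 168 fragments at IFI6 in the libraries labelled IFI6 and no positions, so this cannot be told apart from a lack of overexpression at 24 h after irradiation.

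Libraries 1 and 2 labelled IFI6 held 101 and 345 genes at least 4-fold above every other library. Depth is argued against: library 1 lay within the depth range of the NC libraries, and 344 of the 345 genes of library 2 stayed after thinning to 2165208 fragments. Keratinocytes are argued against by their abundant transcripts, with KRT5 and KRT14 listed at 0 beside TP63 at 73.1 FPKM, and 2 of 10 markers 4-fold above the other libraries; a value of 0 in this table can be a failed estimate. Fragments piled on a short part of a gene could raise its FPKM per fragment where the estimate assigned them to a shorter transcript. Over genes chosen by fragments, the median of this value relative to the other libraries was 0.977 and 0.979 in libraries 1 and 2. It was 2.38 and 1.76 over genes chosen by FPKM, a choice that itself favours high ratios. Over genes chosen by fragments the quartiles were 0.759 and 2.31 in library 1 and 0.770 and 1.775 in library 2. Where the length used for a gene stays the same, piling leaves this ratio unchanged, so the medians cannot decide on piled fragments. The upper quartiles also leave them open for a part of these genes. A response to the construct would be shared, but 1.53% of the 391 genes 4-fold above each NC library in library 2 were so in a second library labelled IFI6; RNA from other cells or libraries stays open as untested.

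The 5 lists differed by camera's preset correlation. With an estimated correlation none of them passed, on the values as deposited (adjusted p = 0.887 for each), with the GC trend removed (smallest 0.625) or without libraries 1 and 2 (smallest 0.543). With each library's GC trend removed they still passed at the preset correlation, with adjusted p of 0.000485 for histones, 0.0180 for glycolysis, 0.0352 for mitochondrially encoded genes, 0.0238 for nuclear oxidative phosphorylation and 0.0449 for cholesterol synthesis, so GC content is argued against as the whole cause. For 3 of the 5 lists, the histones, glycolysis and mitochondrially encoded genes, libraries 1 and 2 labelled IFI6 are argued against too, as these passed in the same direction without either and without both at the preset correlation. Of these 3, glycolysis and the mitochondrially encoded genes were lost without library 3 labelled IFI6 (camera adjusted p = 0.0619 and 0.0747). The histones still passed there. Nuclear oxidative phosphorylation was lost without library 2 alone (adjusted p = 0.111) but passed without both (0.0126), and cholesterol synthesis was lost without both (0.121). Both lists were also lost without library 3 and without NC replicate 2, 3 or 4, so their loss does not single out libraries 1 and 2. Having fewer libraries did not always lose them either. By camera at the preset correlation, the nuclear list passed without library 1 (adjusted p = 0.00271) and the cholesterol list without library 2 (0.0359). The part of libraries 1 and 2 was thus not settled. Ribosomal proteins, not among the 5, passed as lower without both at the preset correlation (adjusted p = 2.70e-06, against 0.321 with all libraries) but not at an estimated correlation (0.543). Chance is not excluded: 3 of the 35 splits of the 8 libraries gave at least 5 lists, with 6 as the highest of the other splits. For single genes the real split gave 0, as did all 35 splits, with 0 as the highest of the others, so that count holds nothing for chance to explain. At an unadjusted p under 0.05, the real split gave 1338 genes against 255 to 688 in the other 34 splits, and with median-ratio scaling 987 against 319 to 820. The real split was thus the 1 of 35 with as many genes, so chance is argued against for this count, which names no single gene. With each library's GC trend removed, the real split gave 879 such genes. The other splits were not run on those values, so this holds only for values that carry the trend. A difference that goes with the construct stays open as untested.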

How the results depend on the processing

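IFI6 stayed lower and short of the threshold in all 12 other settings; leaving out single libraries gave log2 differences of -0.60 to -0.29, with exact permutation p of 0.0857 to 0.371. The count of genes passing stayed at 0 with limma under other pseudocounts, filters, scalings, moderation, weights, GC correction and each library left out (0 to 0), and with edgeR under TMM, size factors or no filter. It was 15 with DESeq2 on restored counts, whose filter left 13547 genes without an adjusted p, 30 in limma without libraries 1 and 2 labelled IFI6 and 429 in edgeR without both; the cause was not tested. The last setting and the GC correction were chosen after seeing the data. The number of lists passing was 3 with upper quartile or median-ratio scaling, 8 with quantile normalization, 0 with an estimated correlation, alone or (chosen after seeing the data) within each of 18 other settings, 0 with fry and 2 to 7 when single libraries were left out; the cause was not tested. With the replicate number as a block, 0 genes and 4 lists passed and IFI6 gave -0.43 (exact sign-flip p = 0.5, smallest possible 0.125). No clear pairing by replicate number was seen: same-numbered deviations correlated at 0.004, -0.015, 0.020 and 0.022 in replicates 1 to 4. The highest correlation with another number was 0.031, 0.030, 0.003 and 0.020. Replicates 3 and 4 thus correlated best with their own number and replicates 1 and 2 did not. All these values were small, so shared cultures or days are not excluded. Over 998 further values of the named genes, 15 passed the threshold in the same direction and 1 reversed: CHEK1 at 0.17 in edgeR without libraries 1 and 2 labelled IFI6. Sizes moved more than calls. With all libraries, edgeR's log2 difference was -0.35 for VEGFA, -0.21 for GAPDH and -0.08 for CHEK1, against -0.77, -0.50 and -0.61 in limma. Others grew, such as HSPE1 (1.33 against 0.81) and C10orf2 (-0.85 against -0.62). For lists, 35 calls were lost, 16 gained and 0 reversed. In data simulated at the depth and spread of these libraries, which were not varied apart, limma found 35% of 2-fold and 91% of 4-fold changes. The simulation gave both groups the same spread for each gene. In the real libraries the median SD was 0.24 in NC and 0.40 in those labelled IFI6, so the share found there may differ.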

Other observations

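All genes of this part were chosen after their values were seen, and both of its tests were chosen after the result was seen. The genes far above every other library in library 2 labelled IFI6 held many interferon-stimulated genes. IFI27 was at 2088 FPKM there and at most 0.215 FPKM in the others, DDX60 at 1476 against at most 24.9 FPKM, and IRF9, a transcription factor of interferon signalling, at 481 against at most 21.8 FPKM. RSAD2 was at 241 FPKM and IFIT1 at 361 FPKM in that library, against at most 4.79 and 46.6 FPKM. LCN2, an iron-binding protein, was at 2141 against at most 0.993 FPKM. Of genes known from epithelia, SFN was at 313 against at most 1.38 FPKM, KRT7 at 381 against at most 44.2 FPKM, CLDN1 at 108 against at most 2.07 FPKM and SERPINB5 at 106 against 0 FPKM. CDH1, KRT19 and EPCAM, also known from epithelia, were at 0.0450, 0.443 and 0 FPKM in that library. No list of epithelial genes other than the keratinocyte markers was fixed, so over-representation of such genes was not tested. In library 1 labelled IFI6, the deacetylase SIRT6 was at 3939 against at most 12.3 FPKM, and CA9, a hypoxia-inducible carbonic anhydrase, at 650.2 against at most 5.31 FPKM. The 345 genes of library 2 had a median of 1631 fragments each (quartiles 1050 and 2143).

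Of the 40 interferon-stimulated genes of the list that were expressed, 15 were among the 345 genes of library 2, an odds ratio of 20.5 (95% interval 9.97 to 40.9, Fisher's exact test across genes, adjusted p = 1.04e-11 over 60 tests of lists in libraries 1 and 2). No other list passed in either library. A candidate explanation is an interferon response of the cells behind that library, and 19 of the 40 members were at least 2-fold above the NC mean relative to all genes, but another 19 stayed under 0.5 log2 above it, ISG15 (30.4 FPKM against 44.5 to 65.5 FPKM in NC) and MX1 (1.86 against 1.38 to 4.06 FPKM) among them. A response across the list is therefore argued against, while a partial response or RNA from another source may remain, as a hypothesis on 1 library.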
